A study of Oryza sativa with 12 samples.

How the data were processed

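Labelled RNA from the youngest fully expanded leaves of rice plants aged 2.5 months was hybridised by the authors to 12 Affymetrix rice arrays, 3 for each of 4 groups: WT control, WT drought, osnox2 control and osnox2 drought. The table deposited by the authors holds log2 values for 57258 probe sets, made with MAS5 according to the submitters' processing notes, which give no version. When the log was undone, the mean of all but the lowest and highest 2% of probe sets was 497 or 498 on every array, and between 996 and 1785 probe sets per array stood at the lowest value. No detection calls were used. The values were used without further normalization. For arrays the precision is set by their number, and the median residual SD was 0.418 on the log2 scale with 8 residual degrees of freedom.

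The 64 reporter probe sets were treated as controls and left out of the tests. Of the other 57194, probe sets above their array's median on at least 3 of the 12 arrays were kept, which left 32012. Probe sets were matched to genes through the accessions in the reference annotation of assembly ASM3414082v1: 22436 matched 1 gene, 95 matched several and 34663 matched none. Of the kept probe sets 18636 matched 1 gene, for 15392 genes, of which 2120 have a name in the annotation, and genes without one are given by their locus identifier. Positions are those of that annotation.

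A linear model of the 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and 5 contrasts were tested two-sided: drought against control in WT and in osnox2, osnox2 against WT under control and under drought, and the difference between the drought responses. P values were adjusted by the Benjamini-Hochberg method over the probe sets kept, and an adjusted p under 0.05 was a call. Replicate numbers were not used as a block, since the labels do not say that a number marks a pot. Correlations of the residuals, computed afterwards, were highest with an array of the same number for 6 of the 12 arrays. The fit was tested on simulated data with the same groups, in which 50 of 32012 probe sets were changed by each of 4 sizes. Of changes of 2 on the log2 scale it recovered 54% for drought in WT, 50% for drought in osnox2, 58% for the genotypes under control, 52% for the genotypes under drought and 38% for the interaction. Of changes of 1 it recovered 30%, 28%, 26%, 24% and 16% in the same order. The simulated noise was independent between probe sets and arrays, and no arrays stood apart in it. These shares therefore do not show how the fit behaves with the structure found among the real arrays.

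The genes named in the text follow a rule fixed in advance. Per comparison it takes the 8 largest rises and the 8 largest falls among called probe sets that match 1 gene with a name (the annotation holds no protein descriptions) and whose 2 groups do not overlap, up to 4 called members of each gene list by adjusted p, the NADPH oxidase genes whether called or not, and the 5 smallest p where nothing was called. Genes named outside this rule are said to be chosen after their values were seen, and list members named as examples in a list's account need not have passed. The themes of 31 gene lists (water loss and ABA, heat shock, oxidative stress, photosynthesis, protein synthesis, hormones, defence, cell walls, water and nitrogen transport, cell division, clock and flowering, other tissues) were also fixed in advance, while the symbol patterns that fill them were written after the annotation was opened. The 26 lists with at least 3 measured genes were tested with limma's camera against all other genes, with a preset correlation of 0.01 between genes, 1 probe set per gene, and adjustment over the lists of a comparison. Members were also adjusted over the list alone. A list holds only genes with a matching name in the annotation, so it need not cover a whole gene family. The groups, comparisons, tests, rule for named genes and every alternative other than those for 3 arrays that stood apart were set before the data were examined.

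Alternatives changed 1 choice at a time: no filter or a filter at the 75th percentile, an offset of 16 or 64 added to the signal before log2, quantile normalization, centring on array medians, no intensity trend, only the 2 groups compared, a fold of at least 2 beside the threshold, a block for the replicate number, and each array left out in turn. The lists were also tested with a correlation estimated per list, with limma's fry, and with the mean of all probe sets of a gene. A term for the 3 control arrays that stood apart, and a fit without them, were added after seeing the data. Other splits of the arrays were fitted in the same way. Preparation and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.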

Results

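Gene expression was measured in rice leaves on 12 Affymetrix arrays, in 4 groups of 3 arrays: wild-type plants (WT) and the T-DNA insertion mutant osnox2, each well watered (control, day 0, soil moisture 47.3%) or after 15 days without water (drought, soil moisture 8.5%). WT and osnox2 plants stood in the same pots. Values are log2 MAS5 signals, and the median log2 signal per array lay between 5.08 and 5.43. The number of arrays limits the precision of every value below. Unless stated otherwise, changes are log2 differences of group means ± SE with n = 3 arrays per group. Positions are those of assembly ASM3414082v1. Gene lists hold only genes with a matching name in the annotation, so their values do not stand for whole gene families. Each comparison was also made without 3 control arrays that stood apart, a choice made after seeing the data.

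The largest division among the arrays did not follow the 4 groups. Replicates 1 and 2 of the osnox2 control and replicate 1 of the WT control lay apart from the other 9 arrays on the first principal component, which held 35.8% of the variance. Correlations of these 3 arrays with the other 9 were 0.868 to 0.895, against 0.932 to 0.954 among themselves. Some genes of the circadian clock, chosen after their values were seen, were at different levels on them. LHY, a clock transcription factor of the morning, read 13.51 to 13.79 on the 3 arrays and 7.31 to 8.99 on the other 9. PCL1, a clock gene of the evening, read 5.59 to 6.16 against 14.33 to 14.99. PRR1 read 9.13 to 9.34 against 11.92 to 12.67, and PRR73 14.37 to 14.47 against 13.49 to 13.72. PRR37 read 13.01 to 13.17 against 12.52 to 12.97, and GI 13.71 to 13.83 against 13.96 to 14.32. Of the 7 measured clock genes only PRR95 overlapped, at 14.33 to 14.37 against 14.28 to 14.48 on the other 9. The flowering regulator Hd1 read 5.34 to 6.41 against 8.61 to 9.71. The 3 arrays hold 2 of the 3 osnox2 control arrays and 1 of the 3 WT control arrays, so they enter every comparison with a control group, and they enter the comparison under drought through the shared estimate of the spread. Without them the osnox2 control keeps 1 array, which is assumed to vary like the other groups, and the WT control keeps 2.

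**Figure D1:**
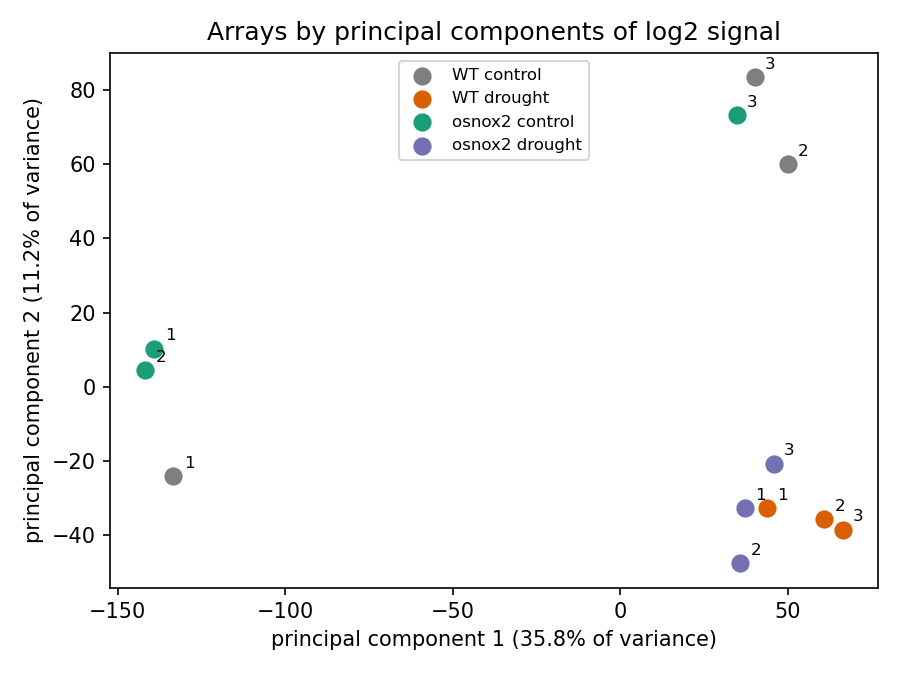
The first and second principal components of the 12 arrays, coloured by group and numbered by replicate. The 3 control arrays that stand apart lie between -141.8 and -133.4 on the first component. The first component holds 35.8% of the variance and the second 11.2%.

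**Figure D2:**
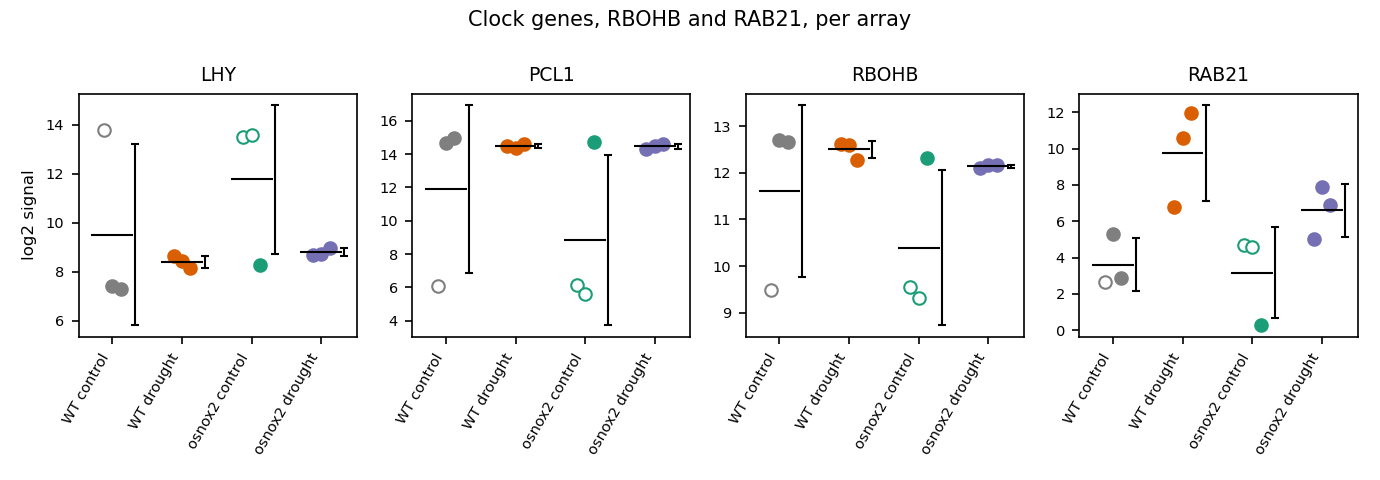
Log2 signal of LHY, PCL1, RBOHB and RAB21 on each array by group, with the group mean (line), the SD (bar) and open circles for the 3 control arrays that stand apart. RBOHB lies between 9.32 and 9.55 on these 3 arrays and between 12.11 and 12.70 on the other 9.

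The study's title names OsRbohA, a plasma membrane NADPH oxidase, as its subject. The annotation used here gives no gene that name, so no value is given for the disrupted gene itself. The 1 NADPH oxidase gene found by its symbol was RBOHB (chromosome 1, 14667234 to 14673667). It did not pass the test in any comparison. Its change with drought was 0.88 ± 0.89 in WT (adjusted p = 0.780) and 1.75 ± 0.89 in osnox2 (adjusted p = 0.319). Its osnox2 minus WT difference was -1.22 ± 0.89 under control conditions and -0.36 ± 0.89 under drought. RBOHB was low on the 3 arrays that stood apart, and without them its change with drought was -0.18 ± 0.11 in WT and -0.17 ± 0.14 in osnox2.

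The drought response of WT plants asks which transcripts a 15-day loss of soil water changed in the leaf. The small heat shock protein genes HSP18.0 (chromosome 1, 4459827 to 4460659) and hsp17.9 (chromosome 3, 8855768 to 8856759) rose, by 2.23 ± 0.24 (adjusted p = 0.0129) and by 1.98 ± 0.14 (adjusted p = 8.4e-04). The gene of the chloroplast copper/zinc superoxide dismutase, sodCp (chromosome 8, 28280148 to 28283373), rose by 1.0 ± 0.12 (adjusted p = 0.0218), while the copper transporter gene COPT1 (chromosome 1, 33128929 to 33129782) fell by 2.54 ± 0.32 (adjusted p = 0.0257). The germin-like protein gene GER4 rose by 5.72 ± 0.82 (adjusted p = 0.0388), a value that rests on a dim control signal and was 2.94 with an offset of 64. D53-L fell by 0.97 ± 0.13 (adjusted p = 0.0279). LOC4341792 (chromosome 6, 28542018 to 28545278), chosen after its values were seen, rose by 2.03 ± 0.20. In all, 27 probe sets were higher and 15 lower of 32012 tested with limma, and 3461 had an unadjusted p under 0.05. The arrays of both groups were fully separated for all 42 of these and for 5759 of all 32012 probe sets tested, where chance gives 10%.

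Of 22 measured genes for enzymes that scavenge reactive oxygen species 1 rose, and 2 rose and 1 fell adjusted over the list alone, with a mean of 0.23 (camera adjusted p = 0.338). Of the 42 measured genes for heat shock proteins and heat stress factors, 2 rose, none fell and the others did not pass the test over all probe sets. Adjusted over the list alone, 11 rose and 2 fell, and the list's mean change was 0.82 (camera adjusted p = 3.9e-05, adjusted p = 0.346 with an estimated correlation). None of the 6 genes for LEA proteins and dehydrins, which accumulate in drying cells, passed over all probe sets, while 4 rose when adjusted over the list alone. The mean change of these 6 was 4.43 (camera adjusted p = 1.0e-04, adjusted p = 0.346 with an estimated correlation). RAB21 read 6.78, 10.56 and 11.93 on the WT drought arrays and between 2.68 and 5.29 on the WT control arrays. LEA19 changed by a value of 6.82 ± 1.51 (adjusted p = 0.127) and RAB16B by 6.99 ± 2.01 (adjusted p = 0.231), both short of the threshold. These values rest on dim control signals, and with an offset of 64 they were 2.44 and 3.08, and the mean of the list 2.34. Among 22 genes of cytosolic ribosomal proteins 8 rose when adjusted over the list alone, with a mean of 0.25 (camera adjusted p = 2.85e-08, adjusted p = 0.346 with an estimated correlation). The 20 genes of ABA signalling had a mean of 0.66, with 0 calls by limma over all probe sets and 0 adjusted over the list alone (camera adjusted p = 0.0266, adjusted p = 0.440 with an estimated correlation).

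Without the 3 arrays that stood apart, 486 probe sets were higher and 464 lower with drought in WT, and all 42 of the calls above were among them. Heat shock genes then stood out: 15 of 42 rose and 1 fell over all probe sets, and 21 rose and 2 fell adjusted over the list alone. The list's mean was 0.88 (camera adjusted p = 2.6e-09), and this call held with an estimated correlation (adjusted p = 0.0155). HSP18.6 rose by 3.01 ± 0.22, HSP24.1 by 2.50 ± 0.19 and the heat stress factor gene HSFB2A by 2.68 ± 0.44. SodCc2 (chromosome 7, 28303368 to 28305482), for a cytosolic copper/zinc superoxide dismutase, rose by 1.76 ± 0.22, and the transcription factor genes WRKY62 and BZIP23 rose by 1.77 ± 0.24 and 1.68 ± 0.36. The germin-like genes GLP2, GER5, GER8 and GER6 fell, with changes of -3.85, -3.19, -3.03 and -2.61. Of the other lists called with all 12 arrays, the LEA list had a mean of 4.0 (camera adjusted p = 0.0103, adjusted p = 0.722 with an estimated correlation) and the ribosomal list of 0.21 (camera adjusted p = 1.35e-05, adjusted p = 0.693 with an estimated correlation), while ABA signalling was no longer called, with 0.46 (camera adjusted p = 0.0590). Chlorophyll synthesis was called in this fit, with a mean of 0.30 (camera adjusted p = 0.0130, adjusted p = 0.801 with an estimated correlation), against 0.23 with all 12 arrays (camera adjusted p = 0.104). LHY rose by 1.03 ± 0.19 in this fit, where its value with all 12 arrays was -1.11 ± 1.71.

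The count for WT drought moved by more than 1.5 times on omission of each array in turn. It was 80 without WT control replicate 1, 26 without replicate 2 and 7 without replicate 3, and 123, 2 and 15 without WT drought replicates 1, 2 and 3. It was 9, 12 and 197 without osnox2 control replicates 1, 2 and 3, and 9, 9 and 8 without osnox2 drought replicates 1, 2 and 3, arrays that enter through the shared spread.

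The same question was asked of osnox2 plants. COPT1 fell by 2.90 ± 0.32 (adjusted p = 0.00974), and HSP18.0 and hsp17.9 rose by 1.51 ± 0.24 (adjusted p = 0.0311) and 1.43 ± 0.14 (adjusted p = 0.00432). Both superoxide dismutase genes rose, SodCc2 by 2.32 ± 0.27 (adjusted p = 0.0136) and sodCp by 0.79 ± 0.12 (adjusted p = 0.0277). The nitrate transporter gene NRT2.3 rose by 2.52 ± 0.36, JAMYB, a MYB factor that responds to jasmonate, by 2.01 ± 0.30, and NH3 by 1.71 ± 0.28. The histone genes H2B.10, H2B.7 and H2B.11 rose by 0.96, 0.69 and 0.68. HSP18.8 fell by 1.87 ± 0.34 (adjusted p = 0.0462) and a chitinase gene, LOC4348631, by 1.43 ± 0.25. CPK21, for a calcium-dependent protein kinase, rose by 3.76 ± 0.64 (adjusted p = 0.0390), but with an offset of 64 the value was 0.45. LOC4324081 (chromosome 1, 3007527 to 3009193), chosen after its values were seen, rose 107-fold (log2 6.74 ± 0.50).

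In this comparison 93 probe sets were higher and 77 lower, 5765 had an unadjusted p under 0.05, and the arrays did not overlap for 22.8% of all probe sets, where chance gives 10%. Of the calls in WT, 15 of 27 higher and 7 of 15 lower probe sets were also called in osnox2 in the same direction, where independent calls would share 0.0784 and 0.0361. Both comparisons use the same estimate of the spread for a probe set, so their calls are not independent and the excess overstates their agreement. Among the 42 heat shock genes 2 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone, with a mean of 0.65 (camera adjusted p = 0.0605, or 0.0193 with quantile normalization). Of the 22 genes for scavenging enzymes 2 rose, and 3 rose adjusted over the list alone, with a mean of 0.25 (camera adjusted p = 0.811). Of 31 genes for jasmonate synthesis and signalling 1 rose, and 13 rose and 2 fell adjusted over the list alone. Their mean was 0.90 (camera adjusted p = 0.0329, adjusted p = 0.684 with an estimated correlation). JAZ1 (LOC4348533), a repressor of jasmonate signalling, had a value of 3.35 ± 0.63 (adjusted p = 0.0510). None of the 6 light harvesting genes passed, also adjusted over the list alone, and their mean was -0.60 (camera adjusted p = 0.0329, adjusted p = 0.684 with an estimated correlation), or -0.40 with quantile normalization (camera adjusted p = 0.378). Ribosomal protein genes had a mean of 0.16 (camera adjusted p = 0.0435, adjusted p = 0.698 with an estimated correlation).

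Without the 3 arrays, 342 probe sets were higher and 120 lower in droughted osnox2, against the 1 control array that was left. Of the 170 calls above, 61 were among them. Of the 42 heat shock genes 14 rose and 1 fell, and 23 rose and 1 fell adjusted over the list alone. Their mean was 1.20 (camera adjusted p = 4.1e-12), and the call held with an estimated correlation (adjusted p = 0.00832). HSP18.6 rose by 3.59 ± 0.28, HSP24.1 by 2.95 ± 0.24 and HSFB2A by 3.81 ± 0.55. JAZ7 rose by 3.27 ± 0.45 and the nitrate reductase gene NIA1 by 2.22 ± 0.27. The 21 aquaporin genes turned direction, from a mean of -0.34 with all 12 arrays (camera adjusted p = 0.0828) to 0.69 in this fit (camera adjusted p = 0.00860, adjusted p = 0.892 with an estimated correlation). Of them PIP2-1 and TIP1-1 rose by 1.96 ± 0.28 and 1.52 ± 0.20 here, where their values with all 12 arrays were -0.63 ± 0.94 and -0.03 ± 0.50. LEA and ABA signalling genes were called in this fit with means of 3.59 (camera adjusted p = 0.0163) and 0.80 (camera adjusted p = 0.0138), both at an adjusted p of 0.892 with an estimated correlation, where with all 12 arrays the means were 2.73 (camera adjusted p = 0.0828) and 0.97 (camera adjusted p = 0.0605). The light harvesting mean turned to 0.12 (camera adjusted p = 0.597), the jasmonate mean was 0.42 (camera adjusted p = 0.0832) and the ribosomal mean 0.09 (camera adjusted p = 0.259), so that all 3 calls were lost.

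The count for osnox2 drought was 7, 8 and 5505 without osnox2 control replicates 1, 2 and 3, and 9, 10 and 11 without osnox2 drought replicates 1, 2 and 3. The 5505 set drought against osnox2 control replicates 1 and 2 alone, which both stood apart, and so carry the difference of those arrays. It was 796, 102 and 67 without WT control replicates 1, 2 and 3, and 56 and 81 without WT drought replicates 2 and 3. Drought and the day of harvest go together in both genotypes, since control leaves were taken at day 0 and droughted leaves at day 15.

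**Figure D3:**
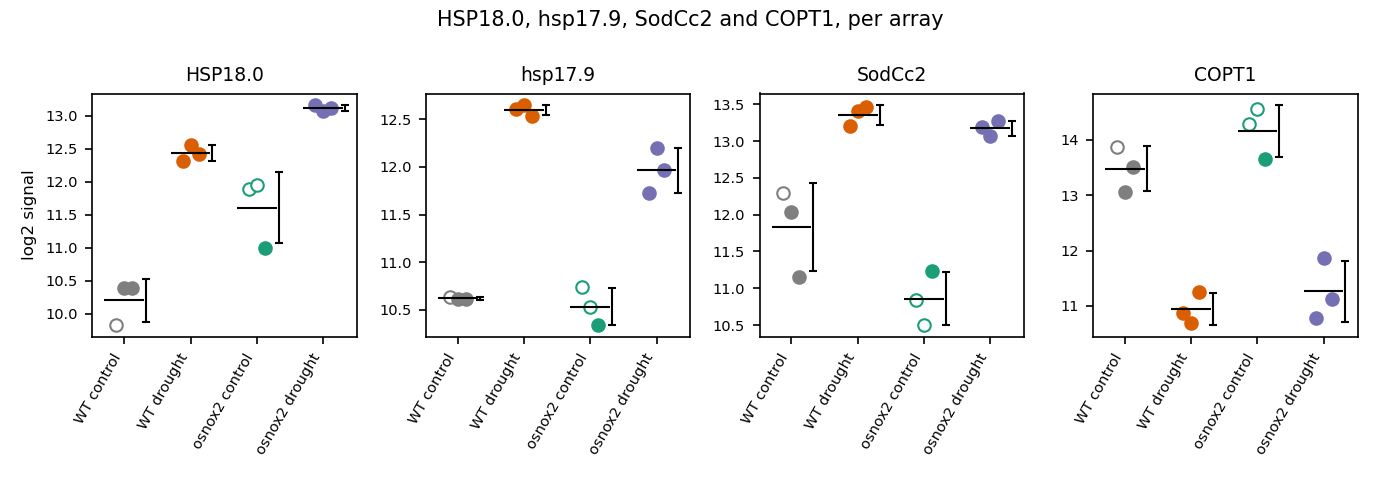
Log2 signal of HSP18.0, hsp17.9, SodCc2 and COPT1 on each array by group, with the group mean (line), the SD (bar) and open circles for the 3 control arrays that stand apart. COPT1 was lower under drought by 2.54 in WT and 2.90 in osnox2.

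The comparison of osnox2 with WT under control conditions asks how watered plants of the mutant differed from WT. The arrays hold no other mutant of the gene. An effect of the disrupted gene therefore cannot be told apart from other differences between osnox2 and WT, here or under drought. LOC4331398 (chromosome 3, 894717 to 896160), chosen after its values were seen, was higher in osnox2 by 8.18 ± 0.14 and 8.64 ± 0.30 on its 2 probe sets, values that were 6.66 and 6.60 with an offset of 64. LOC4340325 (chromosome 6, 4365204 to 4367082), chosen in the same way, was higher by 6.39 ± 0.68, or 4.42 with that offset. The WT control means of these 3 probe sets, 5.08, 4.38 and 4.46, lay within or below the range of the array medians, so the size of these differences depends on signals near background. JAZ2 (LOC4342421, chromosome 7, 2815984 to 2818681), for a repressor of jasmonate signalling, was lower in osnox2 with a difference of -3.12 ± 0.44 (adjusted p = 0.0359). METK3 (chromosome 1, 10682762 to 10685433), for an S-adenosylmethionine synthetase, differed by -2.10 ± 0.31 (adjusted p = 0.0448). CPK21 differed by -4.10 ± 0.64 (adjusted p = 0.0485), a value that was -0.55 with an offset of 64.

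In total 28 probe sets were higher and 14 lower in osnox2 with limma, and 2196 had an unadjusted p under 0.05. The arrays did not overlap for 8.47% of all probe sets, where chance gives 10%. The 31 jasmonate genes had a mean of -0.63, with 0 higher and 1 lower over all probe sets and 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00523, adjusted p = 0.510 with an estimated correlation). Means were 0.73 for 15 genes of chlorophyll synthesis (camera adjusted p = 4.5e-07, adjusted p = 0.498 with an estimated correlation) and 0.44 for 6 light harvesting genes (camera adjusted p = 0.00191). They were 0.40 for the heat shock genes (camera adjusted p = 3.0e-04) and 0.10 for ribosomal protein genes (camera adjusted p = 3.1e-04), and for these last 3 lists the adjusted p was 0.510 with an estimated correlation. With quantile normalization the ribosomal mean was 0.03 (camera adjusted p = 0.466). In these 4 lists limma called 0 members over all probe sets, and adjusted over the list alone 2 heat shock genes were higher.

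The 3 arrays that stood apart make up a larger part of the osnox2 control group than of the WT control group. On average chlorophyll synthesis genes were 0.80 higher on them than on the other control arrays, light harvesting genes 0.96 higher and heat shock genes 0.58 higher, while jasmonate genes differed by -0.71. The median absolute differences were 0.45, 0.42, 0.63 and 0.61 in the same order, against 0.42 over all genes. The means for chlorophyll synthesis and light harvesting therefore rest on larger shifts of some members. Without the 3 arrays the means of the osnox2 minus WT difference were 0.10 for chlorophyll synthesis (camera adjusted p = 0.436), -0.04 for light harvesting (camera adjusted p = 0.708), -0.10 for heat shock genes (camera adjusted p = 0.849) and -0.28 for jasmonate genes (camera adjusted p = 0.204). The ribosomal list kept its call, with a mean of 0.14 (camera adjusted p = 0.00381, adjusted p = 0.890 with an estimated correlation). In that fit 20 probe sets were higher and 68 lower, 16 of the 42 calls above among them. METK3 kept its call with -2.50 ± 0.36, JAZ2 (LOC4342421) did not (-2.64 ± 0.66, adjusted p = 0.188), and HSP81-3, for a cytosolic heat shock protein of the HSP90 family, was higher by 1.25 ± 0.12. Aquaporin genes turned direction, from a mean of 0.30 with all 12 arrays (camera adjusted p = 0.252) to -0.61 there, with 7 of 21 lower and 0 higher adjusted over the list alone (camera adjusted p = 1.1e-04, adjusted p = 0.816 with an estimated correlation).

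The count for this comparison was 13, 15 and 1249 without osnox2 control replicates 1, 2 and 3, and 173, 16 and 13 without WT control replicates 1, 2 and 3. The 1249 rest on osnox2 control replicates 1 and 2 alone, which both stood apart. It was 22 and 18 without osnox2 drought replicates 1 and 3, and 24, 21 and 22 without WT drought replicates 1, 2 and 3.

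The genotypes were then compared under drought, where none of the 3 arrays enters the group means. LOC4331398 was again higher in osnox2, by 8.37 ± 0.14 and 8.68 ± 0.30 on its 2 probe sets, and LOC4340325 by 7.54 ± 0.68. With an offset of 64 these values were 6.66, 6.44 and 5.15, since the WT signal was again near background. The potassium transporter gene HAK11 (chromosome 4, 31635801 to 31640943) was lower, with a difference of -0.85 ± 0.13 (adjusted p = 0.0483). METK3 differed by -2.00 ± 0.31 (adjusted p = 0.0533) and missed the threshold. With limma 29 probe sets were higher and 4 lower, and 1607 had an unadjusted p under 0.05. The arrays did not overlap for 16.5% of all probe sets, where chance gives 10%. The control and drought comparisons of the genotypes shared 19 of their higher calls, against 0.0254 for independent calls, and 0 of their lower calls. Here too the calls are not independent, since both comparisons use the same spread. Replicate 2 of the osnox2 drought group carried transcripts that were high on the WT arrays and low on the other osnox2 arrays, at a median of 23.8% of the WT drought signal over 5 probe sets. Without that array 19 probe sets were higher and 11 lower, and 20 of the 33 calls were among them.

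Under drought 25 of the 31 jasmonate genes lay above 0, with a mean of 0.49 (camera adjusted p = 4.7e-04, adjusted p = 0.617 with an estimated correlation). None passed over all probe sets, and adjusted over the list alone 2 were higher and 1 lower. The 6 measured genes with a WRKY name in the annotation, transcription factors of stress and defence, had a mean of 0.59 (camera adjusted p = 0.0233, adjusted p = 0.617 with an estimated correlation). LEA and dehydrin genes had a mean of -1.83, or -1.20 with an offset of 64 (camera adjusted p = 0.0399, adjusted p = 0.794 with an estimated correlation), and RAB21 read 5.01, 7.89 and 6.90 on the osnox2 drought arrays. The 46 auxin-related genes had a mean of -0.18 (camera adjusted p = 0.0399, adjusted p = 0.809 with an estimated correlation). For the WRKY, LEA and auxin lists limma called 0 members, also adjusted over the list alone.

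Without the 3 arrays, which changes the estimate of the spread but not these group means, 114 probe sets were higher and 75 lower, 31 of the 33 calls above among them. Pir7b was higher in osnox2 by 2.86 ± 0.35, HSP24.1 by 1.41 ± 0.17, NIA1 by 1.21 ± 0.19, the ascorbate peroxidase gene APX2 by 1.03 ± 0.13, HSP81-3 by 0.97 ± 0.08 and JAZ6 by 0.70 ± 0.09. METK3 was lower with -2.00 ± 0.24, the aquaporin gene TIP2-2 with -1.01 ± 0.15 and HAK11 with -0.85 ± 0.11. Heat shock genes had a mean of 0.23 with 3 of 42 higher, and 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00933, adjusted p = 0.264 with an estimated correlation). The LEA and auxin lists then had a camera adjusted p of 0.134 and 0.0913, while jasmonate and WRKY genes kept their calls (camera adjusted p = 0.00231 and 0.0268, each at an adjusted p of 0.435 with an estimated correlation). Nitrogen assimilation genes, with a mean of 0.36, were also called (camera adjusted p = 0.0338, adjusted p = 0.387 with an estimated correlation). The count of 33 was 21 and 21 without osnox2 control replicates 1 and 2, 58 and 21 without WT control replicates 1 and 2, 13 and 18 without osnox2 drought replicates 1 and 3, and 15 and 21 without WT drought replicates 1 and 3.

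The interaction asks whether the drought response itself differed between osnox2 and WT. With limma 0 probe sets passed, 1075 had an unadjusted p under 0.05, and the smallest adjusted p was 0.269. That value belonged to LOC4345657 (chromosome 8, 21192202 to 21195137), whose change with drought was larger in osnox2 than in WT by 1.47 ± 0.19. The next 4, at an adjusted p of 0.986, were LOC9266421 (-0.86 ± 0.15), LOC4324081 (3.68 ± 0.70), LOC4325981 (-0.62 ± 0.12) and LOC4339029 (0.95 ± 0.19). RBOHB had an interaction of 0.86 ± 1.25. A difference between the drought calls of the genotypes is therefore not shown for any single gene with all 12 arrays.

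As a list, jasmonate genes had an interaction mean of 1.12, with 25 of 31 above 0 (camera adjusted p = 1.5e-07, adjusted p = 0.333 with an estimated correlation). Adjusted over the list alone 3 were higher and 0 lower. JAZ7 had a value of 3.31 ± 1.01, JAZ5 (LOC4333065) of 1.48 ± 0.39 and JAZ6 of 1.07 ± 0.26, each at an adjusted p of 0.986 over all probe sets. Chlorophyll synthesis genes had a mean of -0.71 (camera adjusted p = 5.8e-05, adjusted p = 0.580 with an estimated correlation) and light harvesting genes of -0.54 (camera adjusted p = 6.0e-04, adjusted p = 0.617 with an estimated correlation). Ribosomal protein genes had a mean of -0.09 (camera adjusted p = 0.00730, adjusted p = 0.617 with an estimated correlation), which turned to 0.01 with quantile normalization (camera adjusted p = 0.980). For these last 3 lists limma called 0 members, also adjusted over the list alone.

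Without the 3 arrays the jasmonate mean was 0.77 with 24 of 31 above 0 (camera adjusted p = 0.00110, adjusted p = 0.494 with an estimated correlation), and JAZ7 had a value of 4.46 ± 0.57 (adjusted p = 0.0824). The means were -0.08 for chlorophyll synthesis (camera adjusted p = 0.604) and -0.07 for light harvesting (camera adjusted p = 0.776), while the ribosomal list kept its call with -0.13 (camera adjusted p = 0.0112, adjusted p = 0.984 with an estimated correlation). The 17 nitrogen assimilation genes had a mean of 0.71 (camera adjusted p = 0.00240, adjusted p = 0.261 with an estimated correlation), against 0.27 with all 12 arrays (camera adjusted p = 0.642). Aquaporin genes turned direction, from -0.48 with all 12 arrays (camera adjusted p = 0.0804) to 0.43 (camera adjusted p = 0.0128, adjusted p = 0.984 with an estimated correlation). In that fit 8 probe sets were higher and 0 lower, and without osnox2 control replicate 3 alone 46 passed. The directions given above for lists with all 12 arrays did not turn with quantile normalization or with centring on array medians, other than that of the ribosomal proteins, and no scaling moved the median change of all genes by more than 0.1 from its value without it.

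**Figure D4:**
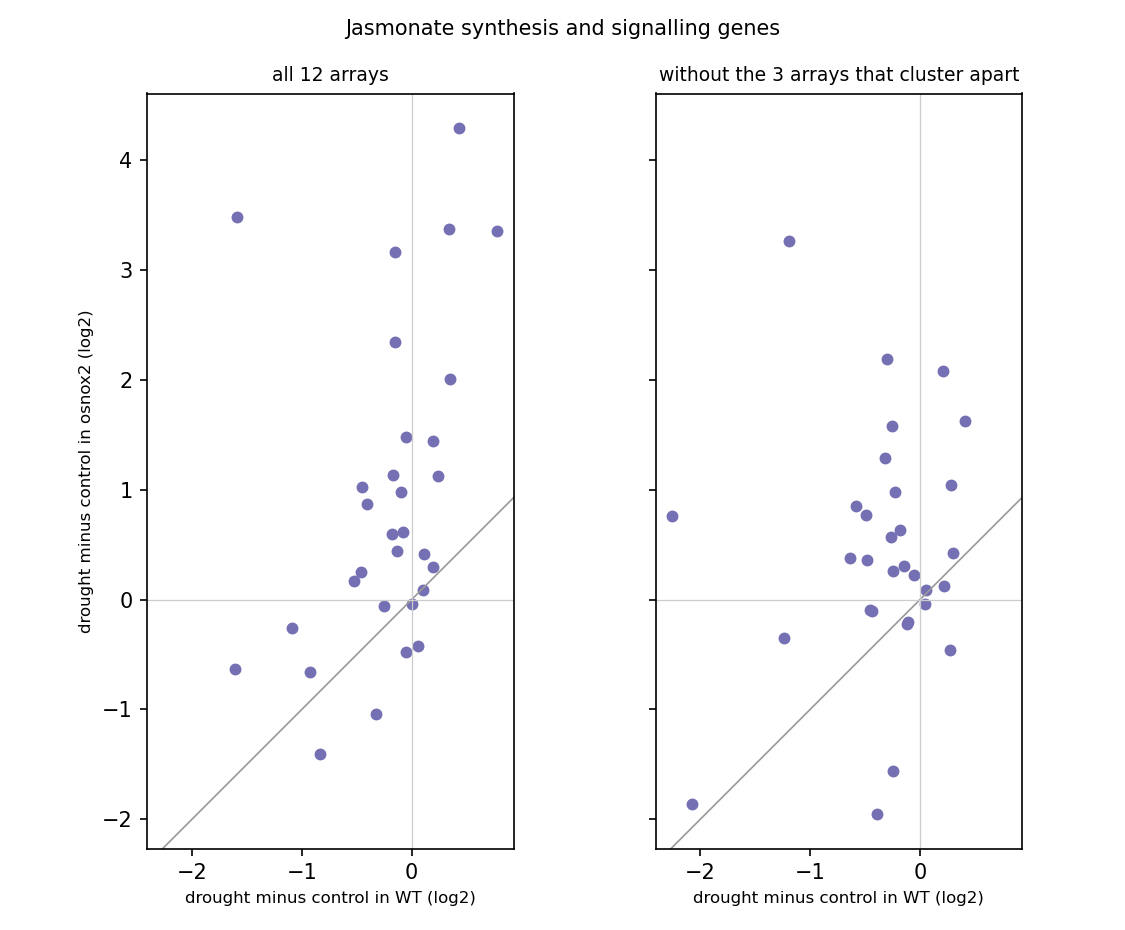
Change with drought in osnox2 against that in WT, both in log2 units, for genes of jasmonate synthesis and signalling (points), with all 12 arrays and without the 3 that stand apart. The diagonal marks an equal change, and 25 of the 31 genes lie above it with all 12 arrays and 24 without the 3.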

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

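The tests in this part were chosen only after the results were seen, other than the splits of the arrays into other groups, which were planned.

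Replicates 1 and 2 of the osnox2 control and replicate 1 of the WT control differed from the other 9 arrays more than drought or genotype did. A swap of genotype labels between control arrays is argued against, since each of these 3 arrays lay nearer its own genotype at 93.3% or more of 15 probe sets that part the genotypes. The 75th percentile of the signal was lower on these 3 arrays (8.59 to 8.62) than on the other 9 (8.72 to 8.82), while their counts of probe sets at the lowest value lay within the range of the others. Array brightness is argued against as the whole cause by quantile normalization, which gives every array the same distribution. With it there were 9476 calls between these 3 and the other 3 control arrays, against 9721 without it. Harvest at another time of day may account for it, as LHY and PCL1 differed in opposite directions. Of the 7 measured clock genes all but PRR95 lay outside the range of the other 9 arrays, though very many other probe sets differed too. The median absolute difference of the clock list was 0.80, rank 10 of 26 lists, with 1.49 for the highest. This rank cannot decide the matter, since a median does not reflect the size of the largest shifts. LHY and PCL1 were looked up because they stood out. The labels give no hour of harvest, so this stays open, as does any other difference between the plants, and no biological explanation from the groups was tested.

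Replicate 2 of the osnox2 drought group carried transcripts that the other osnox2 arrays lacked. LOC4334900 (chromosome 4) read 11.22 there, against 1.89 to 4.02 on the other osnox2 arrays and a WT mean of 13.34, and LOC4334952 (chromosome 4) read 8.17 against 0.54 to 2.77 and a WT mean of 10.66. RNA of WT plants mixed into that sample is a candidate explanation, since 5 probe sets gave a median of 23.8% of the WT drought signal (10.7% to 44.0%), while the highest median on another osnox2 array was 0.244% (single probe sets reached 12.8% on osnox2 drought replicate 3 and 6.90% on osnox2 control replicate 2), and without this array 19 probe sets were higher and 11 lower in osnox2 under drought, against 29 and 4 with it, 20 calls being shared. A single segregating chromosome segment is argued against as the source of all of them, since the probe sets that match 1 gene lay on 2 chromosomes. That argument rests on 1 gene, LOC4324163 on chromosome 1, which had the lowest share (10.7%). LOC4334900 (253051 to 254113) and LOC4334952 (1091305 to 1093405) lay near each other on chromosome 4, and the probe sets that match no gene have no position. A segment on chromosome 4 therefore stays open for these. Segregation at more than 1 place was not tested and also stays open. The annotation does not show whether LOC4324163 is the gene that the T-DNA disrupts, in which case its signal would mark an intact copy.

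The drought response of 3 gene lists differed between osnox2 and WT by limma's camera: the mean interaction was -0.54 for light harvesting, -0.71 for chlorophyll synthesis and 1.12 for jasmonate synthesis and signalling, and none held with an estimated correlation (adjusted p = 0.617, 0.580 and 0.333). The uneven share of the 3 apart control arrays between the genotypes may account for the light harvesting and chlorophyll lists, whose means were -0.0686 and -0.0825 without the 3 arrays. For jasmonate genes the mean was 0.77 without them, a value that rests on 1 osnox2 control array, so an uneven share cannot be told apart from a difference between the genotypes. That difference, which the design names, stays open for all 3 lists.

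Ribosomal protein genes also differed in their drought response by camera, with a mean interaction of -0.0909. This call did not hold with an estimated correlation, and with quantile normalization the mean was 0.01 (camera adjusted p = 0.980). A reporter probe set that stands outside the comparisons read 12.80 on average on the osnox2 arrays (12.45 to 13.32) and 0.73 to 2.97 on the WT arrays. The labels do not say what the inserted T-DNA carries, so whether this probe set reads a part of it is not known. Another reporter probe set read 6.98 on average on the osnox2 arrays (6.12 to 7.86) and 0.33 to 4.60 on the WT arrays.

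In other splits of the same 6 arrays, the real split gave 42 calls for drought in WT and the highest other split 0, and the real split for drought in osnox2 gave 170 and the highest other 0 (in each, 1 of 10 splits gave as many calls). For the genotypes under control the real split gave 42 and the highest other 9721, so 2 of 10 gave as many, and that other split put the 3 apart arrays against the remaining 3, which points to a structure of the arrays. For the genotypes under drought the real split gave 33 and the highest other 2 (1 of 10). The 10 splits of each comparison are too few for a share under 0.05. For the interaction, all 100 splits drawn gave at least the 0 calls of the real one, which excludes nothing, and the highest gave 7455, which points to the same structure.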

How the results depend on the processing

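The alternatives that treat the 3 apart control arrays were chosen only after the results were seen. The test of other choices was planned, and the cause of a change was not tested unless its construction shows it. The count for drought against control in WT was 42, and it was 25 with no filter, 66 with quantile normalization, 11 with no intensity trend and 2 with only the 2 groups compared. For drought against control in osnox2 (170) it was 102 with no filter, 77 with no intensity trend and 5 with only the 2 groups compared. For osnox2 against WT under control (42) it was 21 with the filter at the 75th percentile and 15 with only the 2 groups compared. For osnox2 against WT under drought (33) it was 17 with that filter, 50 with the offset of 64 and 80 with only the 2 groups compared. Fits of only 2 groups estimate the spread from fewer arrays.

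A replicate block left 18 calls for drought in WT, 93 for drought in osnox2 and 17 for the genotypes under control, and 13 named genes passed, against 29 without a block. The residuals do not settle whether replicate numbers pair the arrays. The 18 correlations between residuals of arrays with the same number ran from -0.25 to 0.37, 5 of them over 0.1. Those between arrays of different groups and numbers ran from -0.49 to 0.37. For 6 of the 12 arrays the highest correlation was with an array of the same number.

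With a term for the 3 arrays the counts were 864 and 596 for drought in WT and osnox2, and 67 and 178 for the genotypes under control and drought. Without the 3 arrays they were 950, 462, 88 and 189, the interaction gave 8, and 17 named genes passed, against 29 with all arrays. The interaction gave 0 calls by limma under every other alternative that kept all 12 arrays, and 1075 probe sets had an unadjusted p under 0.05. The 20 calls of gene lists became 0 with an estimated correlation and 7 with fry, 4 of them among the 20, and 17 to 22 under the other alternatives, but these were partly different lists: 8 of the 18 called without the 3 arrays, and 14 of the 22 called with the term, were among the 20. Quantile normalization ended the calls of ribosomal proteins for the genotypes under control (camera adjusted p = 0.466) and for the interaction (0.980) and of light harvesting for drought in osnox2 (0.378), and 5 further lists passed, such as heat shock genes for drought in osnox2 (0.0193) and nitrogen assimilation for drought in WT (0.0410). Of the named genes 3 lost their call with quantile normalization, 9 with no filter and 2 with the offset of 16.

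Leaving out 1 array at a time gave 2 to 197 calls for drought in WT, 7 to 5505 for drought in osnox2, 13 to 1249 for the genotypes under control, 13 to 58 for the genotypes under drought and 0 to 46 for the interaction, with 4 to 32 named genes passing. The lowest counts were without WT drought replicate 2, osnox2 control replicate 1, osnox2 control replicate 1 or WT control replicate 3, and osnox2 drought replicate 1. The highest were without osnox2 control replicate 3, or WT control replicate 1 for the genotypes under drought. Without osnox2 control replicate 3 the osnox2 control holds only replicates 1 and 2, both among the 3 apart arrays. Comparisons with that group then carry the difference of those arrays from the others.

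RBOHB, which passed in no comparison with all 12 arrays, turned direction. Its drought change in WT was -0.18 without WT control replicate 1, -0.13 with the term and -0.18 without the 3 arrays, and its highest value, 1.43, was without WT control replicate 2. Its drought change in osnox2 was -0.28 with the term and -0.17 without the 3, and its interaction was -0.15 with the term. Without osnox2 control replicate 3 its drought change in osnox2 was 2.71 ± 0.77 and passed (limma adjusted p = 0.0395), as did the interactions of LOC4345657 (1.44) and LOC4324081 (4.27). That omission leaves only osnox2 control replicates 1 and 2, both among the 3 apart arrays. RBOHB read 9.55 and 9.32 on them and 12.11 to 12.16 on the osnox2 drought arrays, so its change there is the shift of the apart arrays. The light harvesting list turned without the 3 arrays for drought in osnox2 (camera adjusted p = 0.597) and for the genotypes under control (camera adjusted p = 0.708). The mean of 2 called lists changed sign while the direction of camera's test was not reversed: the heat shock mean for the genotypes under control was -0.10 without the 3 arrays, and the ribosomal mean of the interaction was 0.01 with quantile normalization. Low signals widen log2 changes, so values of dim genes depend on the offset.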

Other observations

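The tests of this part were chosen only after the values were seen.

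Among the lists, chlorophyll breakdown and senescence (5 genes) and ABA synthesis and breakdown (3 genes) differed most between the 3 apart control arrays and the other control arrays. Their median absolute log2 differences were 1.49 and 1.39, against 0.42 over all genes. These medians rest on few genes, and the mean difference of the ABA list was 0.02, so its members did not shift in the same direction. Aquaporin genes were higher on the 3 arrays by a mean of 0.94, and genes of pathogenesis-related proteins and phytoalexin synthesis differed by -0.82. Reference genes in common use and cytosolic ribosomal protein genes differed least, with medians of 0.17 and 0.09.

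Over all 12 arrays, 146 probe sets had every osnox2 array above every WT array and 119 had every WT array above every osnox2 array, where 69.3 would be expected by chance for both directions together. Of these, 10 had a gap of more than 3 on the log2 scale, all of them higher in osnox2, LOC4331398 among them. The absence of such gaps with WT higher rests on osnox2 drought replicate 2: without that array, 5 probe sets had every WT array at least 3 above every other osnox2 array. The count higher in osnox2 was not taken without that array.

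With all 12 arrays and the main settings, limma's camera called the lists of these themes in no comparison: nitrogen assimilation (smallest adjusted p = 0.0633, but 0.0410 for drought in WT and 0.0464 for the genotypes under drought with quantile normalization), aquaporins (0.0804), histones and cell division (0.0828), pathogenesis-related proteins (0.0883), NAC factors (0.101), cytokinin and gibberellin (0.154), Rubisco and the Calvin cycle (0.154) and AP2/ERF factors (0.175). Camera also called nitrogen assimilation for drought in WT with a replicate block (0.0256) and with the mean of probe sets (0.0345). It called NAC factors for the genotypes under drought with no filter (0.0357). With the term for the 3 arrays it called pathogenesis-related proteins for the genotypes under control (0.00283), nitrogen assimilation for the genotypes under drought (0.0176) and both for the interaction (0.0303). For the other lists not described in a comparison, the clock, flowering, cell wall and sugar lists among them, it lay between 0.475 and 0.811. The lists of seed storage proteins and of meristem, guard cell and root genes held 2 and 1 measured genes and were not tested.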
